A study of Mus musculus with 6 samples.

How the data were processed

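RNA was measured by sequencing in 6 libraries of proliferating myeloid cells derived from induced pluripotent stem cells of C57BL/6 mice. Unmodified cells (pMC), cells transduced with IFN-α (IFNa_pMC) and unmodified cells given recombinant IFN-α at 10000 U/mL (pMC_rIFNa) each have 2 libraries. All cultures lasted 24 h with 2000000 cells per well of a 6-well plate, and the libraries were made with a stranded mRNA kit. Per the labels, the authors converted and demultiplexed the reads with bcl2fastq and CASAVA 1.8.2, checked and trimmed them with FastQC and Trimmomatic 0.36, aligned them with TopHat2 2.1.1 and quantified them with Cufflinks 2.2.1, naming build mm9. The deposited values are FPKM, fragments per kilobase of transcript scaled to the fragments of the library, computed by the authors for each library, with no scaling across libraries stated. Each file lists the same 37611 Ensembl genes with a symbol and an interval, printed here as mm9 positions counted from 1. The files hold no read counts, status flags or confidence limits, so the depth is unknown and no interval or floor based on counts was computed.

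Differences were tested with limma 3.58.1 in R 4.3.3. FPKM values were used as deposited, with a pseudocount of 1, on the log2 scale, so the size of a change from or to values near 0 depends on the pseudocount. Genes with an FPKM of at least 1 in at least 2 of the 6 libraries were tested, which left 2509. One model with 3 group means was fitted to the 6 libraries, with a trend in the prior variance, and left 3 residual degrees of freedom. The prior added 2.08. A difference was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. The 3 comparisons were transduced against unmodified cells, recombinant-treated against untreated cells, and transduced against recombinant-treated cells. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values may measure technical spread alone. On simulated data with 200 changed genes in each of 20 datasets, the test found 34.8% of changes of 1 on the log2 scale, 75.5% of changes of 2 and 91.4% of changes of 3, and 4.7% of its calls were unchanged genes.

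The 29 gene lists, the test, the filter, the rule for named genes and the other settings tried were chosen before the data were examined. The lists cover interferon response, antigen presentation, cytokines, cell death, growth, metabolism, stress, housekeeping genes and markers of myeloid and other cell types, 443 genes in all. Lists with at least 3 tested genes were compared with the other tested genes by limma's camera with a preset correlation of 0.01, by camera with the correlation estimated from the data, and by fry, a rotation test of the list alone. List counts are also given adjusted over the list alone. For a list with a lone tested position-matched member this is the unadjusted p. Per comparison, the named genes were the 10 largest rises and the 10 largest falls among called genes whose libraries did not overlap between groups, up to 4 called members of each list or otherwise its 2 most abundant members, and a set of interferon-related genes named in every comparison. Symbols of predicted or numbered genes were skipped.

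The intervals were compared with the position of the same Ensembl gene in GENCODE M21, an annotation of GRCm38, without converting either. The offset of a gene was the difference of its start or end, taken as the commonest difference among the 10 rows on either side and the row itself where start and end differed. Intervals longer than 1000000 bp and more than 3 times the gene's own length were given no position. Rows with an offset of at most 1000 bp are called position-matched, and the others displaced. This step was chosen after the data were examined, because most rows, those of Actb and Gapdh included, carried no signal. The rule for named genes was then also applied within position-matched rows, and only those rows are described as the genes they name.

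Other settings, chosen before the data were examined, changed the pseudocount, the filter, the scaling, the variance model, the libraries in the fit, a block for the replicate number, a minimum change of 1 on the log2 scale, and the library left out. Settings added after seeing the data used position-matched rows alone, rows within 10 bp alone, libraries rescaled to a sum of 1000000 without small RNA rows, and 1 unmodified library for each comparison with unmodified cells, both ways round. The correlation and covariance of the comparisons with unmodified cells were set beside those of 100 simulated datasets in which unchanged groups share the control libraries. Those groups gave almost no calls, so shared calls were set beside 100 other datasets, a test chosen after seeing the data. In these the changes called in each comparison were placed at random among rows of similar level in unmodified cells, in 10 bins, and the groups shared the control libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.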

Results

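Gene expression was measured in proliferating myeloid cells grown from mouse induced pluripotent stem cells, with 2 libraries each of unmodified cells, IFN-α-transduced cells and unmodified cells cultured with recombinant IFN-α. The deposited FPKM values summed to 1695009 and 737593 in the unmodified libraries 01 and 02, to 1545127 and 1330263 in the transduced libraries, and to 836879 and 1273611 in the recombinant-treated libraries. Depth is unknown because the files give no counts. The ratio of FPKM values under 1 that recurred most often across genes put the depth of the transduced library 02 at 0.619 of that of the unmodified library 01, and the other 4 libraries between 0.863 and 1.02. A row named for the small nuclear RNA U6 held 46.7% of the summed FPKM in unmodified library 01. A row of that name held 56.3% and 52.4% in transduced libraries 01 and 02, and 33.6% in recombinant-treated library 02. FPKM divides by transcript length, so these are not shares of the reads. In the other 2 libraries mt-Co1, a mitochondrial cytochrome oxidase gene, had the highest value. Libraries of a group differed by a median of 0.17 on the log2 scale in unmodified cells, 0.10 in transduced cells and 0.10 in recombinant-treated cells over the 694 position-matched genes tested.

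Of 37611 genes listed, 31978 were at 0 in all 6 libraries, and 2509 passed the filter. Among protein-coding genes whose mm9 position in the files coincides within 10 bp with the GRCm38 position, 287 of 500 (57.4%) had a mean FPKM of at least 10, against 377 of 18604 (2.03%) of those displaced by more than 20 kb. Position-matched rows numbered 1700, of which 694 were tested, 347 of them on chromosome 16, 118 on chromosome 19 and 72 on chromosome 8. Coding rows with a mean FPKM of at least 10 were 45.5% at 10 to 100 bp and 31.7% at 100 to 1000 bp. The larger the offset within the class, the less surely a row reports the gene it names. The offset was 113 bp for Cd47, Ccdc80, Zbtb20 and Gpr15, and 245 bp for Ifnar1, Ifnar2, Runx1, Adamts1, Samsn1 and Dnajc28. It was 754 bp for Asb13, Pfkp and Idi1. The 1685 displaced rows and the 130 rows with no position that passed the filter are counted below and not read as the genes they name. Most genes central to the interferon response fall outside what can be read: Isg15, Ifit1, Mx1, Rsad2, Usp18, Irf7, Irf9, Cxcl10, Ccl5, H2-K1, Cd274, Mki67 and Csf1r were listed at 0 in all 6 libraries, every one at a displaced position. B2m, a component of MHC class I, was listed at 0.71 and 0.70 in library 01 of the unmodified and transduced cells and at 0 in the other 4. The type I interferon genes were listed at 0 as well, except Ifnz with 0.66 in unmodified library 02, 0.65 in transduced library 01, and 0.38 and 0.38 in the recombinant-treated libraries, so expression of the IFN-α transgene cannot be read from these values.

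**Figure D1:**
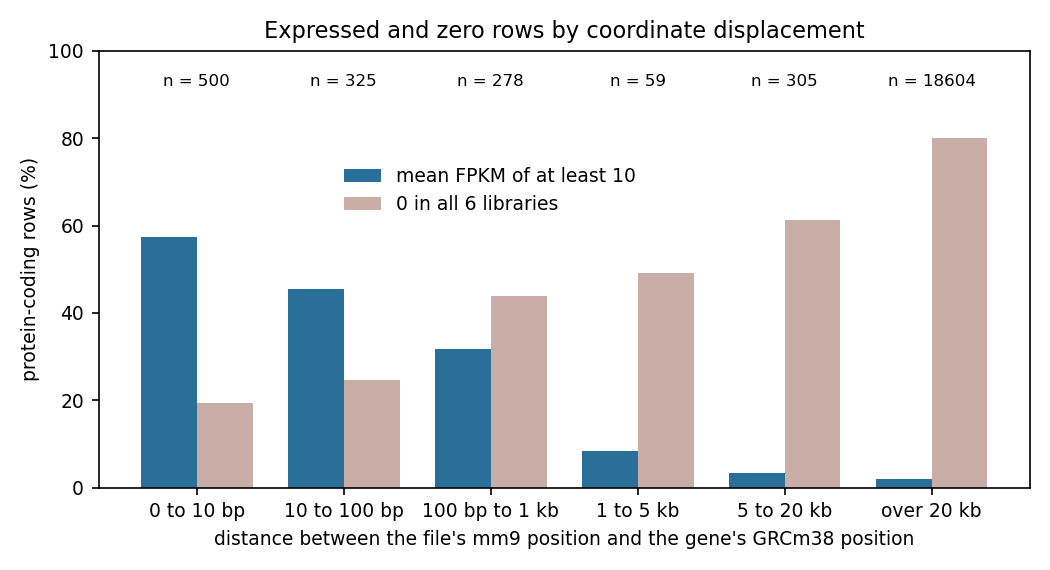
Percent of protein-coding rows with a mean FPKM of at least 10 (blue) and at 0 in all 6 libraries (brown), by the distance in bp between the mm9 position in the files and the GRCm38 position of the same gene; n is the number of rows. The expressed share is 57.4% within 10 bp and 2.03% beyond 20 kb, and the share at 0 is 19.4% and 80.1%.

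The comparison of transduced with unmodified cells asks which genes differ in cells that carry the IFN-α gene. Genes of the antiviral list were higher in the transduced cells, and so were the secreted proteases Mmp3 and Mmp12. Rtp4, an interferon-induced chaperone of membrane receptors, was listed at 0 and 0.90 FPKM in the unmodified libraries and at 844 ± 16.6 (SD, n = 2) in the transduced cells. Mmp3, a matrix metalloproteinase, rose from 0.38 ± 0.18 FPKM (SD, n = 2) to 313 ± 22.9 (SD, n = 2), a log2 fold change of 7.83 with a limma adjusted p of 7.49e-05. The unmodified values lie below the pseudocount of 1, so this size depends on it, and was 8.49 with a pseudocount of 0.5 and 9.39 with 0.1. Mmp12, the macrophage elastase, rose from 367 ± 40.4 FPKM to 4475 ± 31.6 (SD, n = 2 in each), a log2 fold change of 3.61. Bdh1, a mitochondrial enzyme of ketone body metabolism, fell from 77.1 ± 11.5 FPKM to 1.13 ± 0.16 (SD, n = 2 in each), a log2 fold change of -5.19 with an adjusted p of 0.000128.

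Of the antiviral effector list, 35 genes, 4 position-matched members were tested in the transduced cells and all 4 rose, as they did adjusted over the list alone. Beside Rtp4 (log2 fold change 9.26) these were Parp14 (3.35) and Parp9 (2.57), both ADP-ribosyltransferase family members, and Dtx3l (2.37), the ubiquitin ligase that pairs with Parp9. Parp9 and Dtx3l share 1 interval in the files, so their values are not fully separate measurements. The list ranked above the other position-matched genes by camera with an adjusted p of 4.47e-05, and with an adjusted p of 0.117 with an estimated correlation. Among receptor and signalling genes, Socs1, a feedback inhibitor of cytokine signalling, rose by 4.33 on the log2 scale, while the receptor chains Ifnar2 and Ifnar1 fell by 0.90 and fell by 0.37. The same 3 calls stood adjusted over the list alone. The genes moved apart, so the list median was -0.37 and camera gave an adjusted p of 0.578 downwards, while fry gave an adjusted p of 0.0466 upwards. The Ifnar1 call was lost whichever of the 6 libraries was left out (adjusted p 0.0511 to 0.18), and the Ifnar2 call without unmodified library 01, unmodified library 02 or transduced library 02 (up to 0.0562).

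Casp4, the caspase of the noncanonical inflammasome, and Casp1, which processes interleukin-1β, rose by 3.20 and 1.78 in the transduced cells. They were 2 of 3 tested members of the cell death list, also when adjusted over the list alone, and Casp12 was listed at 0 in both groups. The list had a camera adjusted p of 0.0160, and an adjusted p of 0.182 with an estimated correlation. Cd80, a costimulatory ligand, rose by 1.68, while Cd47 and Cd86 had log2 fold changes of 0.27 and 0.12 with adjusted p of 0.0592 and 0.563. Adjusted over the list alone, 2 of these 3 genes of the costimulatory and checkpoint ligand list passed. The list had a camera adjusted p of 0.0525. Ciita, the master regulator of MHC class II transcription, rose by 3.32, from 1.71 and 2.56 FPKM in the unmodified libraries to 31.4 and 28.6 in the transduced ones. Tested members of other lists that fell were Cyp51 of cholesterol synthesis (-0.32), Runx1 (-0.33) and the neutrophil collagenase Mmp8 (-0.72). The values of Mcm4 (-0.26), the stress gene Sdf2l1 (-0.39), the glycolytic gene Pfkp (0.11) and the cholesterol gene Idi1 (-0.18) did not pass. Adjusted over their list alone, Cyp51 and Idi1 were both called lower. Mcm4 and Sdf2l1 are the lone tested position-matched members of their lists. Their unadjusted limma p was under 0.05, which is no adjusted call. The Runx1 call was lost without any 1 of the 6 libraries (adjusted p 0.0528 to 0.137), the Cyp51 call without any 1 library other than unmodified library 02 (up to 0.184), and the Mmp8 call without transduced library 02 (0.0503).

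Other large rises in transduced cells fell outside the lists. Efemp2, which encodes fibulin-4, was listed at 0 in all 4 other libraries and at 36.4 and 52.5 FPKM in the transduced libraries. Emp2, a membrane protein, was at 0 in the other 4 libraries and at 15.8 and 15.5 in these, and Yap1, the coactivator of the Hippo pathway, at 0 and at 11.8 and 10.7. Col4a1, a basement membrane collagen chain, rose by 4.02 and Ltbp3, a latent TGF-β binding protein, was listed at 0.15 and 0 in unmodified libraries and at 15.7 and 17.3 in transduced ones. Beside Bdh1, the falls by rule within position-matched rows were Asb13, Zbtb20, Kbtbd11, Car2, Ccdc80, Retn, Rasgrp2, Adamts1 and Itgb5. Among them Kbtbd11 fell by 1.90 and Ccdc80 fell by 1.62, with adjusted p of 0.00123 and 0.00197. Calls of Car2, Adamts1 and Itgb5 were lost without any 1 of the 6 libraries (adjusted p up to 0.195, 0.139 and 0.184). Those of Zbtb20 and Retn were lost without either library of the 2 groups compared (up to 0.0991 and 0.187), that of Rasgrp2 without any 1 transduced or recombinant-treated library (up to 0.106), and that of Asb13 without transduced library 02 (0.0522).

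Over all tested rows, 178 were higher and 132 lower in transduced cells, of which 89 and 73 were position-matched. Leaving out transduced library 01 gave 81 and 36, and leaving out transduced library 02 gave 72 and 19. The count of lower rows was also 66 without unmodified library 01, and 67 and 70 without recombinant-treated libraries 01 and 02. Quantile normalization gave 167 higher and 226 lower, and rescaling to a sum of 1000000 gave 53 and 34. Of the genes described above, the latter ended the calls of Dtx3l (adjusted p 0.0503), Casp1 (0.334), Cd80 (0.462), Ifnar1 (0.953), Ifnar2 (0.528), Cyp51 (0.962), Runx1 (0.956) and Mmp8 (0.68). It also ended those of Retn, Ccdc80, Zbtb20, Rasgrp2, Car2, Itgb5 and Adamts1 (0.0765 to 0.361). Rescaling without small RNA rows, chosen after seeing the data, gave 369 and 98 and ended the calls of Ifnar1, Cyp51 and Runx1. A pseudocount of 0.1 ended the call of Retn (adjusted p 0.0865). The median of all tested rows moved to -0.27 under rescaling to a sum of 1000000 and to 0.21 without small RNA rows, from 0.02.

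The comparison of recombinant-treated with untreated cells gives the response to added IFN-α. Genes of the antiviral list rose again, and the transcription factor Batf2 and the feedback inhibitor Socs1 were among the largest rises. Parp14 rose from 56.8 ± 10.3 FPKM to 5694 ± 50.6 (SD, n = 2 in each), a log2 fold change of 6.63 with a limma adjusted p of 1.9e-05. Batf2, of the AP-1 family, was listed at 0 in both untreated libraries and at 379 and 339 FPKM in the treated ones. Socs1 was listed at 0.42 and 0 in untreated libraries and at 149 and 154 in treated ones. Gpr15, a leukocyte homing receptor, rose from 0.59 ± 0.28 FPKM to 35.6 ± 2.44 (SD, n = 2 in each).

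All 4 tested position-matched members of the antiviral list rose after recombinant IFN-α, as they did adjusted over the list alone. The log2 fold changes were 9.37 for Rtp4, 6.63 for Parp14, 4.69 for Parp9 and 3.99 for Dtx3l. Camera gave the list an adjusted p of 4.04e-05, and an adjusted p of 0.117 with an estimated correlation. Casp4 rose by 3.91 and Casp1 by 2.13, while Casp12, listed at 0 in all other libraries, was at 1.38 and 1.16 FPKM after treatment. The list of these 3 cell death genes, all called higher, had a camera adjusted p of 0.00389, and an adjusted p of 0.182 with an estimated correlation. Cd47, which signals against phagocytosis, rose by 1.48, Cd86 by 1.08 and Cd80 by 0.94. All 3 tested genes of the costimulatory and checkpoint ligand list thus rose. None of the 3 calls held with libraries rescaled to a sum of 1000000 (adjusted p 0.167, 0.481 and 0.66). This list had a camera adjusted p of 0.00982, and an adjusted p of 0.182 with an estimated correlation. Ciita rose by 2.44. Adjusted over the list alone, the counts of the cell death list and of the costimulatory and checkpoint ligand list were the same. The Casp12 call was lost without any 1 of the untreated and treated libraries (adjusted p up to 0.0879).

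Socs1, described above, and Ifnar1 (log2 fold change 0.46) rose after recombinant IFN-α, and Ifnar2 had a value of 0.19 with an adjusted p of 0.393. The count, 2 of 3, was the same adjusted over the list alone. This list had a camera adjusted p of 0.0455, and an adjusted p of 0.182 with an estimated correlation. Sdf2l1, which assists protein folding in the endoplasmic reticulum, rose by 0.53 and Pfkp, a phosphofructokinase, by 0.82. Cyp51, Idi1, Mcm4, Mmp8 and Runx1 had values of 0.19, 0.22, 0.05, 0.13 and -0.17 and did not pass. Adjusted over their list alone, Cyp51 and Idi1 were called higher. Runx1, the lone tested position-matched member of its list, had an unadjusted limma p under 0.05. Calls of Ifnar1 and Sdf2l1 were lost without any 1 library other than unmodified library 01 (adjusted p up to 0.119 and 0.121), and that of Pfkp without any 1 library other than unmodified library 02 (up to 0.18).

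Outside the lists, Mkx, a homeobox factor, rose by 3.18 and Col4a2, a collagen chain that shares its interval with Col4a1, by 3.17 after recombinant IFN-α. Il7, a lymphocyte growth factor, rose from 0.33 ± 0.26 FPKM to 7.99 ± 0.32 (SD, n = 2 in each), and Asb13 rose by 2.56. The Il7 call was lost without any 1 untreated or treated library (adjusted p up to 0.117). The falls by rule within position-matched rows were Lrfn4 (-1.83), Dnajc28 (-1.79), Rin1 (-1.58), Irs2 (-1.57), Fam100a (-1.49), Klhl24 (-1.34), Peli3 (-1.26), Mkl2 (-1.24), Samsn1 (-1.23) and St6gal1 (-1.18). Irs2, a substrate of the insulin receptor, fell from 72.0 ± 8.46 FPKM to 23.5 ± 1.91 (SD, n = 2 in each), with an adjusted p of 0.00143. St6gal1, a sialyltransferase, fell from 98.4 ± 8.58 to 42.9 ± 1.18. All 10 falls lost their call with libraries rescaled to a sum of 1000000 (adjusted p 0.172 for Lrfn4 to 0.647 for Peli3). Of the 4 scalings tried, only this rescaling ended any of these calls. The Peli3 call was lost without any 1 library other than unmodified library 01 (adjusted p up to 0.189).

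Over all tested rows, 272 were higher and 115 lower after recombinant IFN-α, of which 115 and 62 were position-matched. Leaving out recombinant-treated library 01 gave 144 and 40, and leaving out library 02 gave 146 and 36. The count of lower rows was also 68 and 73 without unmodified libraries 01 and 02, and 63 without either transduced library. Quantile normalization gave 238 higher and 248 lower and moved the median of all tested rows to -0.12, from 0.01. Rescaling to a sum of 1000000 gave 107 and 20 and also ended the calls of Casp12 (adjusted p 0.183), Ifnar1 (1), Sdf2l1 (1) and Pfkp (0.8). Rescaling without small RNA rows gave 230 and 185 and ended the call of Pfkp. A pseudocount of 0.1 ended the call of Asb13 (adjusted p 0.0826).

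**Figure D2:**
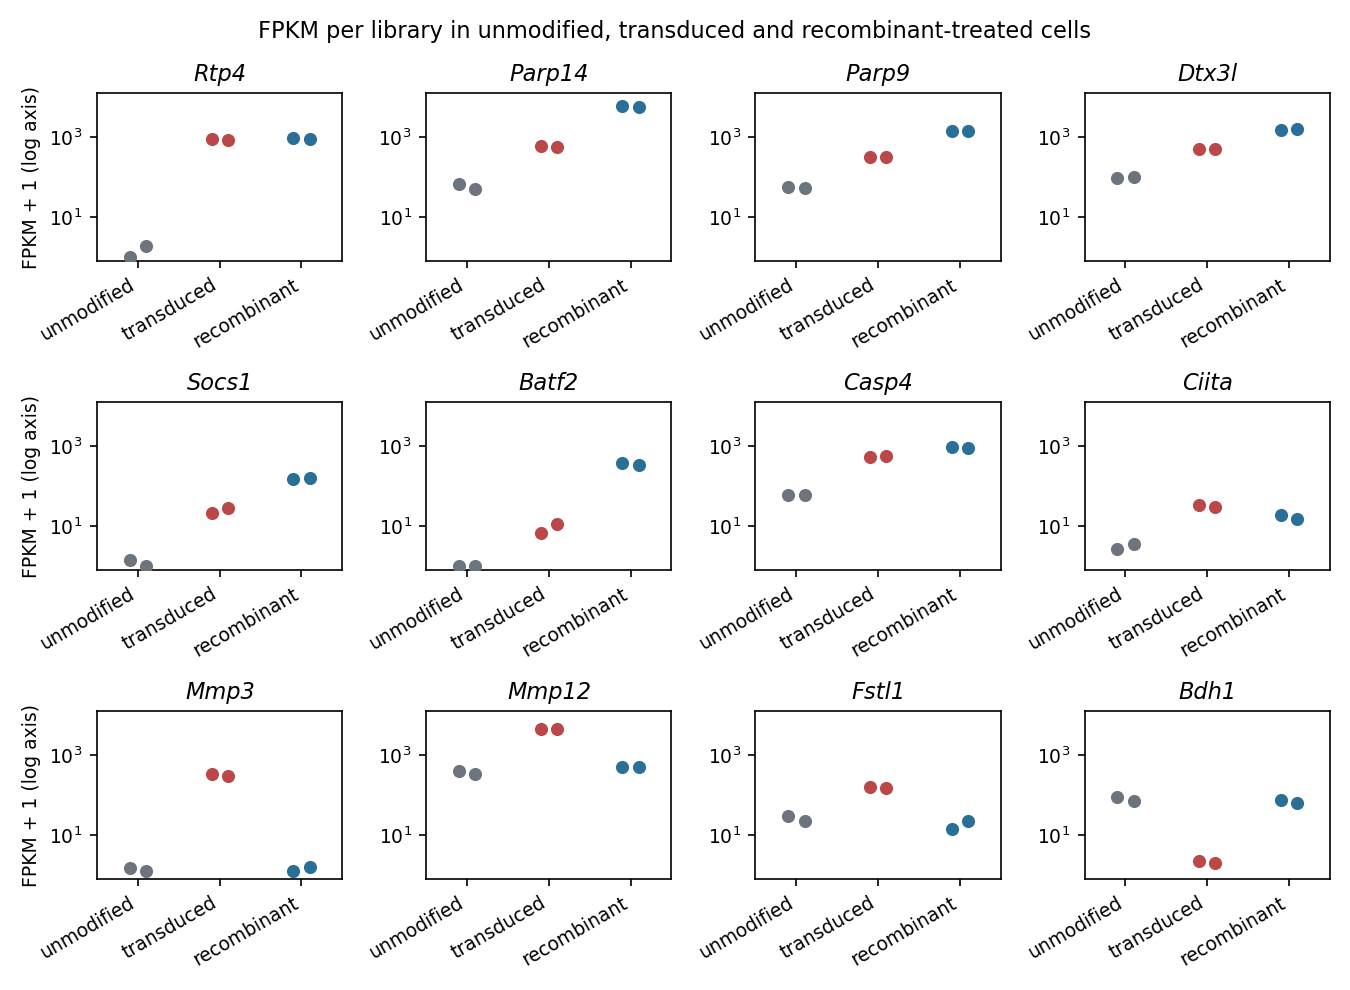
FPKM plus 1 on a log axis for 12 position-matched genes in each library; points are the 2 libraries of unmodified (grey), transduced (red) and recombinant-treated cells (blue). Parp14 reaches 5694 on average after recombinant IFN-α and 582 in transduced cells, while Mmp3 reaches 313 in transduced cells and 0.44 after recombinant IFN-α.

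The direct comparison of transduced with recombinant-treated cells tests where the 2 interferon conditions differ. Of the antiviral genes, 3 of 4 were lower in the transduced cells, while Mmp3 and Mmp12 were higher. Parp14 stood at 582 ± 19.8 FPKM in transduced and 5694 ± 50.6 in recombinant-treated cells (SD, n = 2 in each), a log2 fold change of -3.29 with a limma adjusted p of 0.000255. Rtp4 was an exception, at 844 ± 16.6 and 910 ± 13.8 FPKM, with a log2 fold change of -0.11 ± 0.30 (SE) and an adjusted p of 0.845. Mmp3 stood at 313 ± 22.9 in transduced and 0.44 ± 0.20 in recombinant-treated cells (SD, n = 2 in each), a log2 fold change of 7.78.

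Of the 4 antiviral genes, Parp14, Parp9 (-2.12) and Dtx3l (-1.62) were lower in transduced than in recombinant-treated cells, 3 also when adjusted over the list alone. The list had a camera adjusted p of 0.0129, and an adjusted p of 0.182 with an estimated correlation. Socs1, Ifnar2 and Ifnar1 were all lower, with log2 fold changes of -2.67, -1.09 and -0.83. Their list had a camera adjusted p of 0.0265, and an adjusted p of 0.182 with an estimated correlation. Casp4 (-0.71), Casp1 (-0.36) and Casp12 were lower as well, with a camera adjusted p of 0.0455 for the list, and an adjusted p of 0.212 with an estimated correlation. The Casp1 difference turned to 0.01 with libraries rescaled without small RNA rows, and its call was lost without transduced library 02 or either recombinant-treated library (adjusted p up to 0.0544). That of Casp12 was lost without either transduced library or recombinant-treated library 01 (up to 0.0596). Cd47 (-1.21) and Cd86 (-0.97) were lower and Cd80 (0.74) was higher in transduced cells, with a camera adjusted p of 0.408 for their list. Adjusted over the list alone, the counts of these lists were unchanged. Ciita was higher by 0.88, a call lost without any 1 of the transduced and recombinant-treated libraries (adjusted p up to 0.188).

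Of the genes of other lists, Sdf2l1 (-0.92), Mmp8 (-0.84), Pfkp (-0.71), Cyp51 (-0.51) and Idi1 (-0.40) were lower in transduced than in recombinant-treated cells. Mcm4 (-0.31) and Runx1 (-0.16) did not pass. Each is the lone tested position-matched member of its list and had an unadjusted limma p under 0.05. The 10 largest position-matched differences in favour of transduced cells were those of Mmp3, Efemp2, Ltbp3, Emp2, Col4a1, Yap1, Mmp12, Fstl1, Rin1 and Car13. Fstl1, a secreted glycoprotein, stood at 161 and 151 FPKM in the transduced libraries against 13.3 and 21.3 in the recombinant-treated ones. The 10 in favour of recombinant-treated cells were those of Batf2, Gpr15, Bdh1, Asb13, Parp14, Socs1, Adamts1, Ccdc80, Il7 and Parp9. Batf2 stood at 5.86 and 10.2 FPKM in the transduced libraries and at 379 and 339 in the recombinant-treated ones. Calls were lost for Pfkp without any 1 transduced or recombinant-treated library (adjusted p up to 0.205), for Il7 and Idi1 without transduced library 02 or either recombinant-treated library (up to 0.125 and 0.0843), and for Cyp51 without transduced library 02 or recombinant-treated library 01 (up to 0.0526).

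Over all tested rows, 215 were higher and 348 lower in transduced than in recombinant-treated cells, of which 117 and 163 were position-matched. Leaving out transduced library 01 gave 106 and 195, transduced library 02 gave 91 and 163, recombinant-treated library 01 gave 96 and 159, and recombinant-treated library 02 gave 87 and 159. Rescaling to a sum of 1000000 gave 38 and 128 and moved the median of all tested rows to -0.38, from -0.02. Of the genes described above, it ended the calls of Casp4 (adjusted p 0.353), Casp1, Casp12, Cd47, Cd86, Cd80, Ciita, Ifnar1, Ifnar2, Sdf2l1, Mmp8, Pfkp, Cyp51 and Idi1, from 0.0933 for Cd47 to 0.889 for Cd80. Rescaling without small RNA rows turned the balance, with 498 higher and 226 lower and a median of 0.29, and ended the calls of Casp1, Pfkp, Cyp51 and Idi1. A pseudocount of 0.1 ended the calls of Ciita, Socs1 and Il7 (adjusted p 0.0669, 0.0748 and 0.0757).

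Rtp4, Parp14, Parp9, Dtx3l, Socs1, Casp4, Casp1, Cd80 and Ciita rose in both interferon conditions against unmodified cells. In all, 84 tested rows were higher in both, against 19.3 for independent lists, and 36 of them were position-matched. Of the 84, 38 were higher in recombinant-treated than in transduced cells by the direct test and 12 were higher in transduced cells. Another 32 were lower in both, against 6.05 for independent lists, among them Irs2 and Klhl24. Opposite calls numbered 15 rows higher in transduced and lower in recombinant-treated cells and 13 the other way, and Rin1 (1.37 and -1.58), St6gal1 (1.02 and -1.18), Asb13 (-2.33 and 2.56) and Ccdc80 (-1.62 and 0.74) were among them. With libraries rescaled to a sum of 1000000, Irs2 and Klhl24 were called in neither comparison, nor were Rin1, St6gal1 and Ccdc80, while Asb13 kept both calls. Without either transduced library the calls of Irs2, Klhl24 and Rin1 in transduced cells were lost (adjusted p up to 0.108), Irs2 also without unmodified library 02, and that of Ccdc80 after recombinant IFN-α without any 1 untreated or treated library (up to 0.123). Across genes, which are not independent replicates, the 2 responses had Pearson's r of 0.42 and Spearman's rho of 0.32. Simulated unchanged groups that share the controls gave a higher r, 0.506, so r alone shows no common response. Over position-matched rows r was 0.44, against 0.485 in such groups. The covariance of the 2 responses over all rows was 0.414, against 0.115 in the simulated unchanged groups. Both comparisons use the same 2 control libraries. With 1 control library for each, chosen after seeing the data, 58 rows were higher and 10 lower in both with library 01 for the transduced cells, and 69 and 11 with library 02 for them. Independent lists of those sizes would share 10.7 and 2.85, and 11.6 and 1.92, and r was 0.267 and 0.13. Simulated groups with the called changes placed independently of each other, and with shared controls, gave on average 24 higher in both (at most 36 in 100 datasets) and 8.42 lower in both (at most 14). In a fit of the position-matched rows alone, 50 were higher in both, against 29.1 for independent lists and 26.1 in the simulation (at most 38), and 32 were lower in both, against 14.6 and 13.3 (at most 24). The simulation made fewer calls than the data, 142 and 216 higher in the 2 comparisons over all rows. The count higher in both was 46 and 42 without transduced libraries 01 and 02 and 55 without recombinant-treated library 01. The count lower in both was 10 and 17 without unmodified libraries 01 and 02, 5 and 2 without transduced libraries 01 and 02, and 6 and 8 without recombinant-treated libraries 01 and 02. With libraries rescaled to a sum of 1000000, 25 were higher and 6 lower in both.

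**Figure D3:**
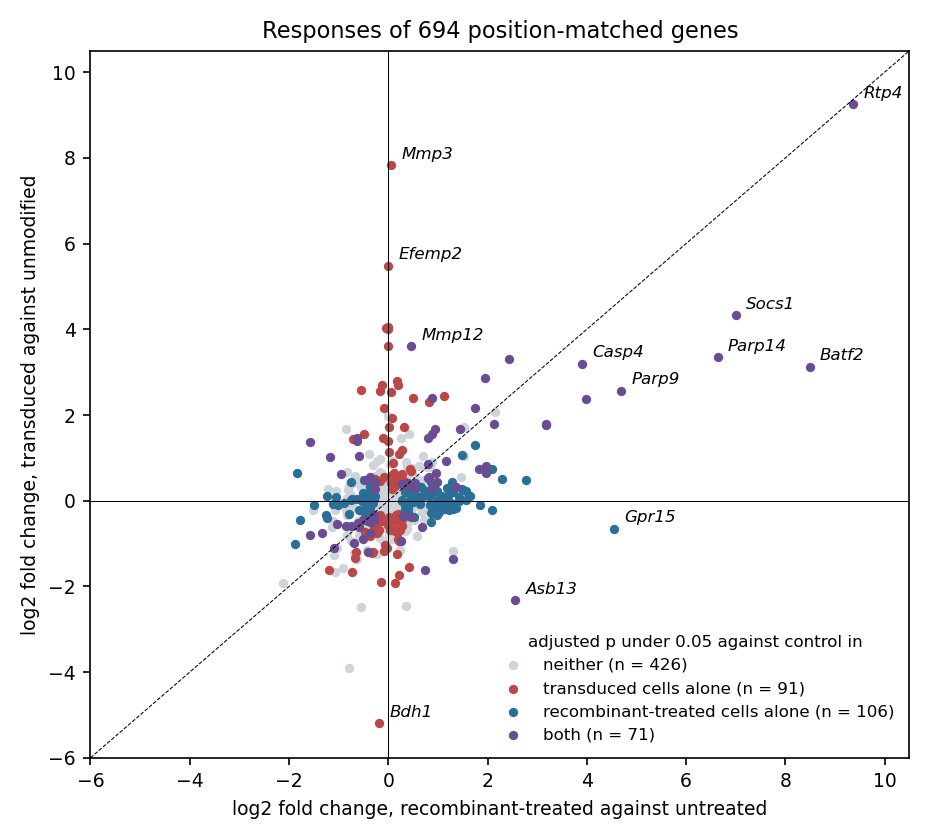
Log2 fold change of 694 position-matched genes in transduced against unmodified cells (vertical axis) and in recombinant-treated against untreated cells (horizontal axis); the dashed line marks equal values. Colours mark the 71 genes called in both comparisons, the 91 called in transduced cells alone and the 106 called in recombinant-treated cells alone. Rtp4 lies near the line, Parp14 and Batf2 below it, and Mmp3 and Efemp2 on the vertical axis.

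The named genes lie at these mm9 positions, counted from 1. On chromosome 16, Rtp4 (ENSMUSG00000033355) spans 23610005 to 23614308, Parp14 (ENSMUSG00000034422) spans 35832960 to 35871630, Parp9 and Dtx3l lie within 35926597 to 36037217, Socs1 spans 10783901 to 10785629, and Bdh1 (ENSMUSG00000046598) spans 31422366 to 31458987. Batf2 lies within 6134374 to 6172476 on chromosome 19. Mmp3 (ENSMUSG00000043613) spans 7445822 to 7455972 and Mmp12 (ENSMUSG00000049723) spans 7344381 to 7388047 on chromosome 9, where Casp4 spans 5308828 to 5336783.

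Of the 29 lists, 9 had at least 3 tested rows and 4 had at least 3 position-matched ones, and 21 of the 443 listed genes had a position-matched tested row. No such row was tested for type I interferon genes, nucleic acid sensors, guanylate-binding proteins, MHC class I genes, chemokines, cytokines, MYC targets, macrophage polarisation genes or housekeeping genes, nor for markers of macrophages, dendritic cells, mast cells, lymphoid cells, erythroid cells, pluripotent cells, fibroblasts, endothelial or epithelial cells, or sex chromosomes. Over all rows, 10 of 27 list tests by camera were called, none of them with an estimated correlation, and 18 by fry. The antiviral list, with 10 tested rows of which 4 are position-matched, had a camera adjusted p of 2.06e-05 in transduced and 2.2e-06 in recombinant-treated cells, and an adjusted p of 0.197 in both with an estimated correlation. The list tests over all rows include displaced rows, which are not read as the genes they name. They are therefore not tests of the listed genes alone. Of the 20 largest rises and falls that the rule names over all rows, 11 were displaced in each comparison with unmodified cells and 7 in the direct comparison, and these are not described.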

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

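All the tests in this part were chosen after the results were seen. Signal was found in tested rows that are counted above but not read as the genes they name. Of these, 14 displaced rows whose mm9 interval, read as GRCm38 positions, covers a gene of the antiviral or guanylate-binding lists were higher after recombinant IFN-α. They are 14 of 19 such rows tested, and 7 of the 19 were higher in transduced cells. They are not 19 separate measurements, since 5 of the 19, 4 of them higher, share 1 interval around Irgm1. Of the 14 rows with an interval of their own, 10 were higher. Some of the 19 rows cover other genes beside the list gene, so their values cannot be assigned to the list gene alone. The row named Ifit2 lies over Ifit1 and Ifit1bl2 in GRCm38. It was listed at 0.64 and 1.08 FPKM in unmodified libraries, at 858 and 814 in transduced ones and at 13940 and 13740 in recombinant-treated ones. The row named Slc6a13, a transporter gene, lies over Usp18, a negative regulator of interferon signalling, and was listed at 0, 0, 14.4, 13.7, 22.5 and 19.5 in the same order. The row named Gm2574 lies over Gbp2, a guanylate-binding GTPase, and was listed at 0 in unmodified libraries, at 0.81 and 0.67 in transduced ones and at 30.3 and 36.9 in recombinant-treated ones. The row named Gm5970 lies over Iigp1, an immunity-related GTPase, and was listed at 0 in the first 4 libraries and at 37.7 and 40.0 after recombinant IFN-α.

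Most genes were listed at 0 while genes at coinciding mm9 and GRCm38 positions carried values. Too few reads would empty near and far positions alike, yet the share of protein-coding genes at 0 was 4.13 times higher beyond 20 kb than within 10 bp, and only 2 of 10 housekeeping genes passed the filter, which argues against genes simply not being expressed. Reads placed on GRCm38 and counted at mm9 gene positions may account for the pattern, since the share of protein-coding genes with a mean FPKM of at least 10 was 28.3 times higher within 10 bp than beyond 20 kb. Displaced rows may then report the gene that lies at their interval in GRCm38, since the 19 rows chosen by position had a median log2 fold change of 3.51 after recombinant IFN-α, against 1.12 for the 8 displaced rows named for such genes, 4 of which are in both sets. Without the 5 rows that share an interval the median was 3.81. No other biological explanation was tested, and the alignments themselves were not used here.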

How the results depend on the processing

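The settings with position-matched rows alone, rows within 10 bp alone, rescaling without small RNA rows, and 1 control library for each comparison with unmodified cells were chosen after seeing the data; the other settings were chosen before. With only 2 libraries per group, each left-out library leaves a lone library that is assumed to vary like the others, and changes under 1 on the log2 scale are mostly missed at this size. A setting restricted to rows with a status flag was not run, since the files hold none. The cause of the changes below was not tested, except that fewer rows are tested within position limits and that a minimum change can only remove calls.

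Counts are given for transduced against unmodified, recombinant-treated against untreated, and transduced against recombinant-treated cells in that order. List calls over all rows include displaced rows, so they are not read as changes of the listed genes. Rescaling to a sum of 1000000 gave 53, 107 and 38 higher and 34, 20 and 128 lower, 25 higher and 6 lower in both, and 5 list calls. Quantile normalization gave 226 and 248 lower in the first and second comparison and 85 lower in both. A minimum log2 fold change of 1 gave 112, 180 and 104 higher, 58, 43 and 204 lower, and 47 higher and 7 lower in both. Using only the 4 libraries of a comparison gave 70 and 63 lower in the first and second and 10 lower in both. Without a variance trend, 83 were lower in the first and 15 in both. The replicate block gave 70 lower in the second and 15 in both, and replicate numbers showed no pairing (r of -0.04 to 0.05 across genes). Without a filter, 72 were lower in the second and 20 in both. The stricter filter gave 4 list calls, camera with an estimated correlation gave 0, and fry gave 18. Position-matched rows alone gave 153 higher in the second, 186 lower in the last and 50 higher in both. Rows within 10 bp alone gave 91, 73 and 93 higher, 66, 50 and 99 lower, 25 higher and 20 lower in both, 3 list calls and a correlation of 0.304. Simulated unchanged groups that share the controls had r of 0.506 over all rows and 0.485 over position-matched rows. Correlations with shared controls, here and below, therefore show no common response by themselves. Rescaling without small RNA rows gave 369 and 498 higher in the first and last, and 185 and 226 lower in the second and last.

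Leaving out 1 library gave 72 to 153, 144 to 213 and 87 to 235 higher, 19 to 105, 36 to 73 and 159 to 346 lower, 42 to 74 higher and 2 to 17 lower in both, 7 to 10 list calls and a correlation of 0.384 to 0.522. With unmodified library 01 as the only control of the transduced cells and 02 as that of the recombinant-treated cells, 58 were higher and 10 lower in both with a correlation of 0.267, and the other way round 69 and 11 with a correlation of 0.13.

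Of the named values, these changed sign. In transduced against unmodified cells, Pfkp was -0.245 with a sum of 1000000, and -0.0914 and -0.024 without library 01 of unmodified or of transduced cells. In recombinant-treated cells, quantile normalization gave -0.108 for Cyp51, -0.221 for Mmp8, -0.105 for Mcm4, -0.134 for Idi1 and -0.233 for mt-Rnr2. Rescaling without small RNA rows gave -0.00957 for Mmp8, -0.0856 for Mcm4 and -0.0388 for mt-Co1, and leaving out 1 library gave -0.0157 to 0.118 for Mcm4 and -0.528 to 0.2 for Clcf1, with all 4 ends reached without an unmodified library. In transduced against recombinant-treated cells, rescaling without small RNA rows gave 0.0445 for Mcm4, 0.206 for Runx1 and 0.00965 for Casp1, and a sum of 1000000 gave -0.232 for mt-Rnr1. None of these but Casp1 was called as deposited. Of the called named values, 24 of 44, 27 of 35 and 33 of 48 kept their call whichever library was left out, and 19, 13 and 22 kept it with a sum of 1000000.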

Other observations

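The lists of matrix metalloproteinase and mitochondrial genes, the other genes named for the first time here, and the test of rescaling to a sum of 1000000 were chosen only after the results were seen; the tests of median-ratio scaling, fibroblast rows, quantile normalization and single libraries were chosen before theirs. Mmp genes lie side by side on chromosome 9, from 7272514 to 7581885 in mm9, and did not move together. In transduced cells, 4 of 6 rose, which were Mmp3, Mmp12, Mmp13 (log2 fold change 2.87) and Mmp10, and Mmp27 (-1.24) and Mmp8 fell. All 6 kept these signs under the 4 scalings tried. Mmp10 was listed at 0 in unmodified libraries and at 2.90 and 5.21 FPKM in transduced ones, a call lost without either unmodified library or transduced library 02 (adjusted p up to 0.0657), and the Mmp8 call was lost without transduced library 02 (0.0503). Calls of Mmp8 and Mmp27 were lost with libraries rescaled to a sum of 1000000 (0.68 and 0.279). Camera gave the family an adjusted p of 0.0751, and an adjusted p of 0.453 with an estimated correlation. After recombinant IFN-α, Mmp13, a collagenase, rose by 1.96 and Mmp12 by 0.46. The Mmp12 call after recombinant IFN-α was lost with a sum of 1000000 (adjusted p 1), under quantile normalization, and without any 1 transduced or recombinant-treated library (up to 0.147). The transcription factor Zeb1 (2.41) and the cytokine gene Clcf1 (2.57) also rose in transduced cells, and the Clcf1 call was lost without either transduced library (adjusted p up to 0.0695) and with a sum of 1000000 (0.0525).

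Mitochondrial transcripts moved in different directions. In transduced cells, 5 of 11 mitochondrially encoded protein genes fell, led by mt-Nd1 (-1.20) and followed by mt-Nd2 (-0.75) and mt-Cytb (-0.74), and 9 of 11 lay below 0, as did 9 or 10 under each of the 4 scalings. The family had a camera adjusted p of 0.00694, and an adjusted p of 0.453 with an estimated correlation. With libraries rescaled to a sum of 1000000, 1 of the 11 was called lower, and under quantile normalization 2 were. The mt-Nd1 and mt-Cytb calls were lost under both (adjusted p 0.31 and 0.725 under the former), and the mt-Nd2 call under the former (0.712). The calls of mt-Nd2 and mt-Cytb were lost without transduced library 02 (adjusted p 0.0571 and 0.0617). The small ribosomal RNA mt-Rnr1 rose by 1.68 in transduced and by 1.44 in recombinant-treated cells, and both calls were lost with a sum of 1000000 (adjusted p 0.475 and 0.228). The large one, mt-Rnr2, fell in transduced cells (-0.52), a call lost with a sum of 1000000, under quantile normalization and without any 1 library other than transduced library 01 (up to 0.0771). Tfrc, the transferrin receptor, fell from 1700 ± 168 FPKM to 824 ± 3.27 (SD, n = 2 in each) after recombinant IFN-α, a log2 fold change of -1.04, a call also lost with a sum of 1000000 (0.748).

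A set of 45 position-matched genes was higher in transduced cells than in both other groups and not called higher after recombinant IFN-α. Mmp3, Efemp2, Col4a1 and Yap1 were among them. A missing call does not show that a gene was unchanged. As deposited, all 6 tested Mmp genes, Mmp3 and Mmp10 of the set included, lay above 0 after recombinant IFN-α. Col4a2, which shares the interval of Col4a1, rose in both conditions (log2 fold change 1.79 and 3.17). The Col4a1 row is therefore not a fully separate measurement. Median-ratio scaling kept 100% of the calls, but its factors of 0.993 to 1.03 move little, so that test leaves library scaling open. With libraries rescaled to a sum of 1000000, which moves them most, the median log2 fold change of the set was 1.08 against 1.40 as deposited, and 95.6% of the set stayed above 0. Only 13 of the 45 calls remained then, as the median standard error rose from 0.167 to 0.639. The sums of the 2 unmodified libraries, 1695009 and 737593, differ, with a row named U6 at 46.7% of the former. With small RNA rows left out of the sums the standard error was 0.17, so those rows account for the widening in this set. Quantile normalization kept 41 of the 45 calls with a median of 1.33, and rescaling without small RNA rows, chosen after seeing the data, kept 45 with 1.67. The set was picked as higher in the same data, and rescaling to a sum of 1000000 moved the median of all tested rows only to -0.27. The median of the set could thus hardly fall to 0. The values show only that these scalings move less than the median of the set, and scaling stays open for its smaller changes. Without transduced library 01, 18 of the 45 stayed called, and 15 without transduced library 02, although all 45 stayed above 0. Fibroblast or feeder cells in the transduced cultures cannot be told apart from a change in the myeloid cells, because 0 displaced tested rows covered only a fibroblast list gene. A difference that came with transduction or with the chosen line, or long exposure to IFN-α, may also underlie the set and was not tested, so no cause is favoured.

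Dtx3l, Parp14, Parp9 and Socs1 rose more after recombinant IFN-α than in transduced cells. The median log2 fold change of the 4 genes between transduced and recombinant-treated cells was -2.25 under quantile normalization and -2.04 with libraries rescaled without small RNA rows, a setting chosen after seeing the data and the nearest to 0 of the 4 scalings. All 4 genes stayed called under each. The set was picked as higher after recombinant IFN-α in the same data, with a median of -2.4 as deposited. The 4 scalings moved the median of all tested rows in this comparison only to between -0.38 and 0.29. The calls could thus hardly be lost, and the values show only that these scalings move less than the median of the set. Parp9 and Dtx3l share an interval, so the 4 genes are not fully separate measurements. The median of the set was -2.5 to -2.3 whichever of the 6 libraries was left out. As the set was picked from these libraries, this shows only that no 1 library set the size of the median. With a pseudocount of 0.1 the Socs1 call was lost (adjusted p 0.0748) and the other 3 held. None of the 4 lies within 10 bp of its GRCm38 position, as the offset is 93 bp for Socs1 and 86 bp for the others, so the setting of rows within 10 bp alone does not test them. A lower dose may account for the difference and was not tested, because the IFN-α concentration of the transduced cultures is not stated.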
